A study of Homo sapiens with 4 samples.

How the data were processed

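CUT&RUN for the transcriptional repressor BCL6 was carried out on nuclei of SUDHL5, an established diffuse large B-cell lymphoma cell line. In CUT&RUN an antibody directs a micrococcal nuclease fusion to the chromatin around its target, and the released fragments are sequenced. The labels name 2 biological replicates with a BCL6 antibody and 2 with normal rabbit IgG, and no treatment is named for any of the 4. Groups and replicate numbers were taken from the sample titles. The BCL6 libraries each came with a peak list. Values of the IgG libraries were not analysed here, so no BCL6 library was compared with an IgG library.

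Per the submitters' processing notes, FastQC, cutadapt, Bowtie2, SAMtools, Picard, MACS2, bedtools and deepTools were used, and the build was hg38. Their versions, settings and order are not given in the sources used here, nor is the control that the peak caller was given. The deposited lists follow the narrowPeak layout of MACS2, and peaks were called per sample and not on pooled samples. Each deposited peak carries a fold enrichment (a ratio of the summit over the local background), −log10 of p and of q, and the position of its summit. The deposited score column held 10 times the −log10 q, cut to a whole number, and was not used further. The smallest −log10 q was 1.31 in each list, which corresponds to a q threshold of 0.05.

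Library sizes are not given in the sources used here. The fold enrichment is (pileup + 1) / (background + 1) and p is the Poisson probability of exceeding the pileup at that background. The whole-number pileup at each summit and its background were therefore solved from the authors' fold enrichment and −log10 p. A pileup was found within 0.001 on the −log10 scale for 5233 of 5237 peaks of replicate 1 and 3532 of 3536 peaks of replicate 2. Statements on pileups cover all peaks on chromosomes 1 to 22 and X, with no filter on this tolerance. The median summit pileup on chromosomes 1 to 22 and X was 23 in replicate 1 and 21 in replicate 2. The exact Poisson 95% interval of a pileup of 23 is 14.6 to 34.5, and that of 21 is 13.0 to 32.1. These intervals cover counting error only, since PCR copies are not independent molecules. The recovered backgrounds fell on multiples of 0.983 in 42.5% of the replicate 1 peaks and on multiples of 0.742 in 44.9% of the replicate 2 peaks. With a tolerance of 0.002, chance gives 0.407% and 0.539% for a step fixed beforehand. The steps were taken from the most frequent background of the same peaks, so the chance share here is higher by an unknown amount. A scaled control library gives such steps, but which library it was is not given.

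Peaks of the lists were merged where they shared at least 1 bp. A merged region that held a peak of each replicate was called reproducible, and its summit was that of the peak with the highest −log10 q. Overlap was compared with 100 placements of the replicate 2 peaks at random positions on the same chromosome, and with 100 sets in which each peak was moved by 10 to 50 kb. Random positions were drawn between the first and the last annotated gene of a chromosome, without excluding assembly gaps. Shares carry Wilson 95% intervals. Agreement in rank used Spearman's rho with 100000 permutations across regions, which are not independent replicates. Strength was summarised by deciles of each list.

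Genes came from a RefSeq table of GRCh38.p14, the same assembly as hg38, with 19974 protein-coding genes on chromosomes 1 to 22 and X. The plan assumed a genome sequence and strands. No genome sequence and no strand were used here, so distances were measured to either annotated end of a gene, and a start cannot be told from a 3′ end. Exons and untranslated regions were not separated, and none of the planned motif tests was run. Summits within 1 kb of an end were counted as near a gene end. Sets were compared with Fisher's exact test, two-sided.

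For 16 gene lists of 388 entries (356 distinct genes), fixed before the data were examined, the share of members with a reproducible summit within 10 kb of either end was compared with that of all other protein-coding genes by Fisher's exact test, two-sided. The p-values were adjusted by the Benjamini-Hochberg method over the lists. All members were found in the gene table, 1 of them under a newer symbol. Genes and regions were named by a rule fixed at the same time. It takes the 10 reproducible regions with the largest fold enrichment, taking the smaller of both replicates, each with its nearest protein-coding gene. It adds up to 4 members of each list with the largest such values, a fixed set (BCL6, PRDM1, CDKN1A, BCL2L11, BBC3, PMAIP1, BMF, IRF4, CCND2 and FOXO3) whatever their values, and the 3 strongest regions of each single-list set. Some genes that the rule names are not reported here. Other names are said to have been chosen after their values were seen.

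The alternatives were reciprocal overlap of at least 50%, summits within 200 bp, −log10 q of at least 5 or 10, lists of equal length, windows of 1, 2 and 50 kb, ends of all annotated genes, and each replicate list alone. The gene body with 5 kb on both sides was compared with 10000 draws of genes within 200 ranks in length.

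The steps were tested on simulated data. The pileup was recovered in 100% of 1000 simulated peaks, and 1000 planted shared regions gave 1000 reproducible regions. The shared peaks were of equal width and overlapped by design, so this count checked only the merging step. In 100 simulated lists of 40 genes, regions were planted at 25% of members, and genes outside all planted lists had them at 5%. Of these lists, 81% passed the adjusted threshold. The comparison genes of each list included members of the other planted lists, so their share was above 5%. Adjustment was over 200 lists, of which 100 were planted. Of 200 lists without any planted, 4.5% had an unadjusted p below 0.05. Apart from the BCL6 targets with 44, the gene lists had 11 to 36 members. How often such smaller lists would pass was not simulated, so the 81% does not apply to them. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.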

Results

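BCL6 occupancy was measured by CUT&RUN in SUDHL5, a diffuse large B-cell lymphoma line, as part of a study of a molecular glue that links lysine acetyltransferases to BCL6. The 2 biological replicates gave 5237 and 3536 peaks with median widths of 454 and 435 bp. The peaks covered 2951 kb of the genome in replicate 1 and 1879 kb in replicate 2. The median fold enrichment given by the authors was 3.55 in replicate 1 and 3.74 in replicate 2, and the highest were 18.8 and 18.2. Read totals are unknown. The middle 50% of summit pileups lay between 18 and 31 in replicate 1 and between 16 and 27 in replicate 2, so a typical peak rests on few fragments. The lowest local background was 1.56 in replicate 1 and 1.22 in replicate 2.

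The first comparison asked which BCL6 regions were found in both replicates. By the smaller of both fold enrichments, the strongest reproducible region lay on chromosome 4 from 73618144 to 73621532. Its summit was inside RASSF6, 602 bp from an end of the gene. The fold enrichment of this region was 13.8 in replicate 1 and 18.2 in replicate 2, with summit pileups of 128 (95% Poisson interval 107 to 152) and 98 (79.6 to 119). A region on chromosome 8 from 108248127 to 108249686 had its summit 250 bp outside EIF3E, which encodes a translation initiation factor subunit, with fold enrichments of 13.4 and 11.8. A region on chromosome 17 from 45190518 to 45191462 lay 20.9 kb from HEXIM2, an inhibitor of the transcription elongation factor P-TEFb, with fold enrichments of 10.9 and 15.7.

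Among the 10 strongest, 2 lay beside histone genes of chromosome 6. The region from 27148200 to 27148901 was 835 bp from H2AC12, with fold enrichments of 10.4 and 10.7. The region from 26233922 to 26236452 was 274 bp from H1-3, with fold enrichments of 9.369 and 9.003. The other 5 summits were not close to a protein-coding gene end. One lay inside KIF13B, 33.9 kb from its end, and the others lay 16.3 kb from MRPS18A, 46.4 kb from PLXNC1, 205 kb from DUSP4 and 304 kb from API5. The smaller of both fold enrichments was 12.1 for the region nearest DUSP4, a phosphatase of MAP kinases, and between 9.12 and 11.3 for the remaining 4.

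In all, 1316 of 7379 merged regions held a peak of each list, while 3887 held a peak of replicate 1 only and 2176 of replicate 2 only. Of the replicate 2 peaks, 1360 (38.5%, Wilson 95% interval 36.9 to 40.1) overlapped a replicate 1 peak, and of the replicate 1 peaks, 1350 (25.8%, 24.6 to 27.0) overlapped a replicate 2 peak. Random placement of the replicate 2 peaks gave a mean of 7.41 overlaps and at most 15 in 100 placements. Moving each by 10 to 50 kb gave a mean of 65.0 and at most 84. The count depends on the matching rule: where 1350 replicate 1 peaks overlapped a replicate 2 peak by at least 1 bp, 763 had a partner with a reciprocal overlap of at least 50%, and 863 had one with summits within 200 bp. With peaks of −log10 q of at least 10 alone, 200 regions were reproducible.

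Whether a peak was found again followed its summit pileup more closely than its fold enrichment. In the lowest decile of replicate 1 by pileup (8 to 14) 3.25% were found in replicate 2, and in the highest (41 to 306) 69.4% (95% interval 65.3 to 73.2). In replicate 2 the share went from 8.24% to 80.7% (76.3 to 84.5). By fold enrichment, the lower 9 deciles of replicate 1 ranged from 19.1% to 28.1% and the highest reached 48.0%. Local backgrounds differed along with pileups. In replicate 1 the median pileup was 31 and the background 7.84 for reproducible regions, against 21 and 5.25 for regions of that list only. In replicate 2 they were 26 and 5.93, against 18 and 4.04. A high pileup therefore reflects local coverage as well as enrichment, and the 2 were not separated here. Peaks with a −log10 q of at least 20 were found in the other list in 116 of 126 cases (92.1%, 86.0 to 95.6) for replicate 1 and 80 of 81 (98.8%, 93.3 to 99.8) for replicate 2.

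**Figure D1:**
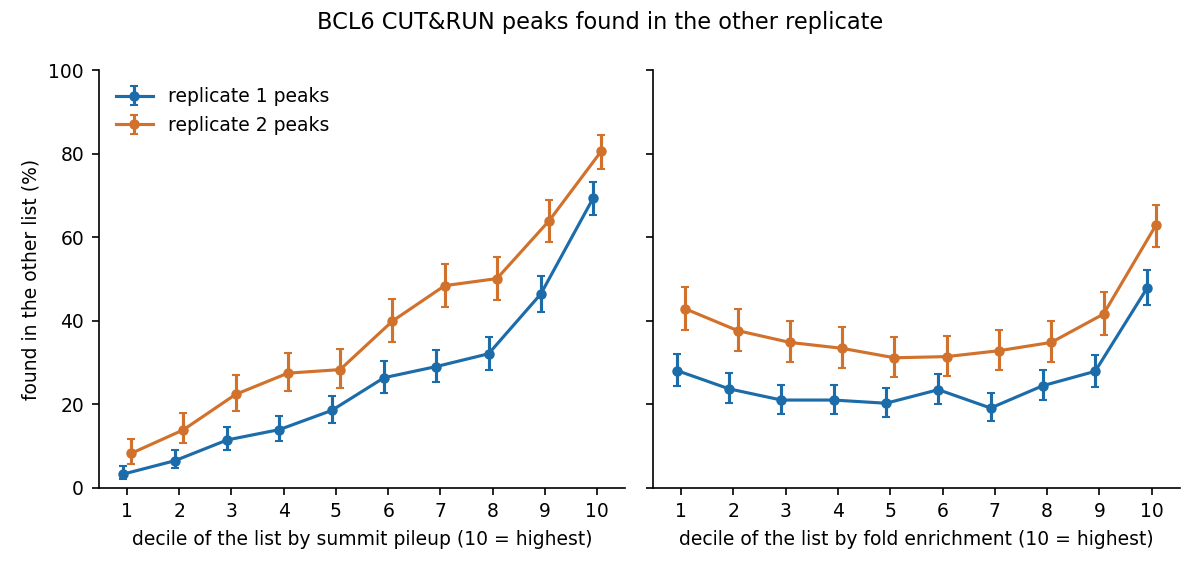
Percent of the peaks of each replicate that overlap a peak of the other (vertical axis) by decile of the list, ranked by summit pileup (left) or by the authors' fold enrichment (right); bars are Wilson 95% intervals. By pileup the share climbs from 3.25% to 69.4% in replicate 1 and from 8.24% to 80.7% in replicate 2, while by fold enrichment there is no such climb below the top decile.

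Of the regions in replicate 1 only, the 3 with the largest fold enrichment lay 78.7 kb from GLI3 (10.0), inside TBC1D19 (9.08) and 308 bp from UCP3 (8.74). Those in replicate 2 only lay 211 bp from WDR17 (11.2), inside STRBP (8.33) and inside OSBPL10, 20.5 kb from ZNF860 (7.83). The summit pileup of the WDR17 region was 47 (95% Poisson interval 34.5 to 62.5), with no replicate 1 peak over it.

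Across the 1311 reproducible regions on chromosomes 1 to 22 and X, the fold enrichments of the replicates ranked alike to a moderate degree, with a Spearman rho of 0.380 (permutation p = 1.0e-05, the smallest that 100000 permutations can give) and a Pearson r of 0.530. For −log10 q rho was 0.469 (permutation p = 1.0e-05). Summit pileups agreed more closely, with a rho of 0.834 (permutation p = 1.0e-05) and a Pearson r of 0.894. These are correlations across regions, which are not independent replicates.

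**Figure D2:**
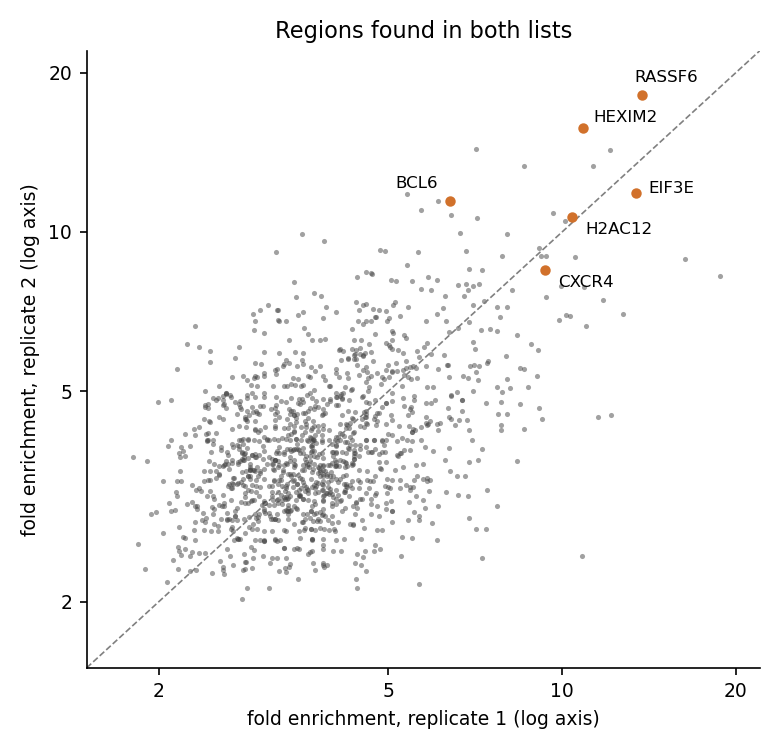
Authors' fold enrichment in replicate 1 (horizontal, log axis) and replicate 2 (vertical, log axis) for the 1311 reproducible regions on chromosomes 1 to 22 and X; the dashed line marks equal values and coloured points are labelled with the nearest gene. RASSF6, HEXIM2, EIF3E and H2AC12 are high in both replicates, and the bulk between 2 and 5 is broad, with a rho of 0.380.

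The position of the regions relative to genes was examined next. Reproducible summits gathered at gene ends: 446 of 1311 (34.02%, Wilson 95% interval 31.5 to 36.6) lay within 1 kb of an annotated end of a protein-coding gene, among them those at EIF3E, H1-3, BCL6 and RASSF6. Random placement gave 2.50% on average and at most 3.51%. Moving each summit by 10 to 50 kb, which keeps its neighbourhood, gave 4.80% on average and at most 6.25%. A further 505 summits (38.5%) lay inside a protein-coding gene away from its ends, against 41.8% for random positions, and 360 (27.5%) lay outside genes, against 55.6%. The regions near gene ends had median summit pileups of 35 and 30 and backgrounds of 9.41 and 7.42, while those elsewhere had pileups of 29 and 24 and backgrounds of 6.88 and 5.19.

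Regions of 1 list only were near gene ends less often than reproducible ones. The share was 26.7% of 3885 for replicate 1 only (odds ratio 1.41, Fisher's exact test, two-sided, adjusted p = 1.22e-06) and 29.9% of 2175 for replicate 2 only (odds ratio 1.21, Fisher's exact adjusted p = 0.0129). Both stayed far above random placement, whose highest values were 3.14% and 3.40%. Neither share separates transcription starts from 3′ ends, because strands were not used.

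Regions at named genes were then compared with those at other genes. Reproducible summits lay within 10 kb of an end of 943 of 19974 protein-coding genes (4.72%). Of 44 genes listed beforehand as known BCL6 targets, 11 had one (25%, Wilson 95% interval 14.6 to 39.4), against 4.68% of other genes (5.35-fold, Fisher's exact adjusted p = 7.17e-05). The 4 with the largest fold enrichment were BCL6, CISH, CD69 and ID2. The region at BCL6 itself spanned chromosome 3 from 187744913 to 187749446, with its summit 132 bp beyond the upper end of the gene. Its fold enrichment was 6.38 in replicate 1 and 11.5 in replicate 2, with pileups of 112 (92.2 to 135) and 87 (69.7 to 107). CISH, a cytokine signalling inhibitor, had fold enrichments of 6.35 and 5.60 at 146 bp. CD69, an early activation marker, had 4.74 and 4.48 at 4.63 kb, and ID2, an inhibitor of basic helix-loop-helix factors, had 4.31 and 5.02 at 712 bp.

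**Figure D3:**
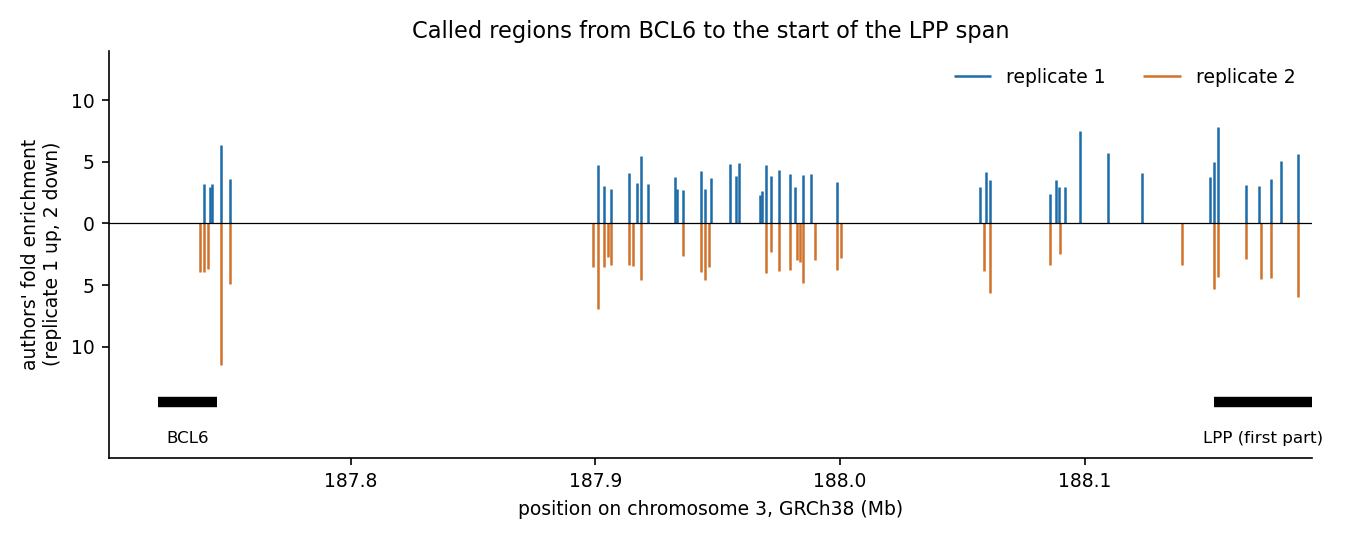
Called regions on chromosome 3 from BCL6 to the first part of LPP (horizontal axis, GRCh38, Mb), each drawn as a line at its midpoint with the authors' fold enrichment (vertical axis) in replicate 1 upward and in replicate 2 downward; black bars are the genes. The region at the upper end of BCL6 reaches 6.38 and 11.5, and a second group of regions, picked after its values were seen, lies between 187898794 and 188000506, where 14 of 34 regions were reproducible.

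Cell cycle arrest and DNA damage checkpoint genes had regions at 5 of 23 (21.7%, 9.66 to 41.9, Fisher's exact adjusted p = 0.0307). The 4 with the largest fold enrichment were the cyclin-dependent kinase inhibitors CDKN2A, CDKN2B and CDKN2C, and BTG2, an antiproliferative gene. CDKN2A and CDKN2B are neighbours on chromosome 9 and share the region from 21993267 to 21994493, with fold enrichments of 4.612 and 5.002. BTG2 had 3.47 and 3.34. With these 2 counted once, 4 of 22 genes had regions (18.2%, 7.31 to 38.5) and the list did not pass (Fisher's exact adjusted p = 0.0860), so the call depends on this shared region. It ended in 6 of 9 alternatives, in each of which fewer members had a region. The fold over other genes, 4.62 in the main test, was 3.30 within 1 kb (8.70%, 2.42 to 26.8, against 2.63%, Fisher's exact adjusted p = 0.374), 6.33 with peaks of −log10 q of at least 5 (13.04%, 4.54 to 32.1, against 2.06%, Fisher's exact adjusted p = 0.0921) and 4.44 without chromosome 12 (20.0%, 8.07 to 41.6, against 4.51%, Fisher's exact adjusted p = 0.0601). Where the cell cycle call held, the fold was 2.66 within 50 kb, 2.87 in replicate 1 alone and 3.10 in replicate 2 alone. The call of the BCL6 targets held in all 9, but counting members at the same regions once left its counts unchanged and so did not test it. The fold of the targets over other genes was lower in single lists, 2.55 in replicate 1 alone and 2.43 in replicate 2 alone. In each replicate alone, several other lists passed with larger shares than the targets, as given below.

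No other list passed after adjustment. Germinal centre genes had regions at 4 of 20 (20.0%, Fisher's exact adjusted p = 0.0696), namely BCL6, LMO2, DAPP1 and ELL3. This list passed in 5 of 9 alternatives, and with a window of 1 kb it and the BCL6 targets were the 2 that did (20.0% against 2.62%, Fisher's exact adjusted p = 0.0133). Plasma cell genes had them at 3 of 15 (20.0%), namely CD38, CD27 and XBP1, a regulator of secretory cells with fold enrichments of 5.92 and 5.87 at 2.38 kb. B cell identity genes had them at 4 of 25 (16.0%), namely FOXP1, BLK, CD22 and CD79B, and NF-kB and CD40 response genes at 4 of 26 (15.4%), namely BIRC3, NFKB1, NFKBIA and NFKBIZ. The Fisher's exact adjusted p was 0.0860 for each of these 3. B cell identity genes passed in 4 of 9 alternatives: 36% within 50 kb, against 9.77% (Fisher's exact adjusted p = 0.00209), 36% for gene bodies with 5 kb on both sides, against 5.88% (permutation adjusted p = 0.00160 against genes of like length), and each replicate list alone. They were at 8% within 1 kb, 4% with peaks of −log10 q of at least 5 and 0% with at least 10. NF-kB and CD40 response genes passed in 2 of 9 and plasma cell genes in 1. Among BCL6 co-repressors and acetyltransferases, the demethylase KDM1A, the co-repressor BCOR and the acetyltransferase KAT2B had regions (3 of 22, 13.6%, Fisher's exact adjusted p = 0.164), and this list passed in 2 of 9.

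Genes that promote apoptosis had regions at 4 of 30 (13.3%, Fisher's exact adjusted p = 0.117) and passed in 2 of 9 alternatives. At BCL2L11, which encodes the BH3-only protein BIM, the region on chromosome 2 from 111119567 to 111120732 had its summit 340 bp outside the gene, with fold enrichments of 3.12 and 2.90. FOXO3 had 4.56 and 4.46 at 5.80 kb, and the BH3-only genes HRK and BMF each had 2.44 in replicate 1, with 3.40 and 4.17 in replicate 2. The −log10 q was 1.65 and 2.24 for HRK and 1.65 and 4.87 for BMF, where the smallest in each list was 1.31. With peaks of −log10 q of at least 5, the list promoting apoptosis was at 0%. Of the genes that oppose apoptosis, BIRC3 and MCL1 had regions (2 of 11, 18.2%, Fisher's exact adjusted p = 0.164), and the list passed in 1 of 9. MCL1 had fold enrichments of 4.99 and 3.29 at 6.03 kb.

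Lists of other cell types did not differ detectably from other genes. Regions were found at 2 of 18 T cell markers (CD3E and LCK, 11.1%), 1 of 16 myeloid markers (CD68, 6.25%), 1 of 26 neuron genes (GRIN1, 3.85%) and 0 of 26 hepatocyte genes (95% interval up to 12.9%). Regions were found at 1 of 26 interferon response genes (3.85%), 1 of 24 chemokine genes (CXCR4, 4.17%) and 1 of 36 ribosomal protein genes (RPL15, 2.78%). The region nearest CXCR4, a chemokine receptor, was strong, with fold enrichments of 9.35 and 8.47 at 8.73 kb. The Fisher's exact adjusted p of these 7 lists was between 0.332 and 1.

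The number of lists past the threshold was 2 with reproducible regions, 7 with a window of 50 kb, T cell markers among them (Fisher's exact adjusted p = 0.0221), 6 with all replicate 2 peaks and 7 with all replicate 1 peaks. In replicate 1 alone, germinal centre genes reached 70.0% and B cell identity genes 68.0%, against 15.1% of other genes (Fisher's exact adjusted p = 4.23e-07 and 5.94e-08). These lists and the cell cycle arrest, NF-kB and co-repressor lists passed in each replicate alone, with larger shares than the BCL6 targets. The lowest was NF-kB, at 42.3% against 38.6% of the targets in replicate 1 and 30.8% against 27.3% in replicate 2. Genes promoting apoptosis passed in replicate 1 alone with a smaller share, 33.3%.

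**Figure D4:**
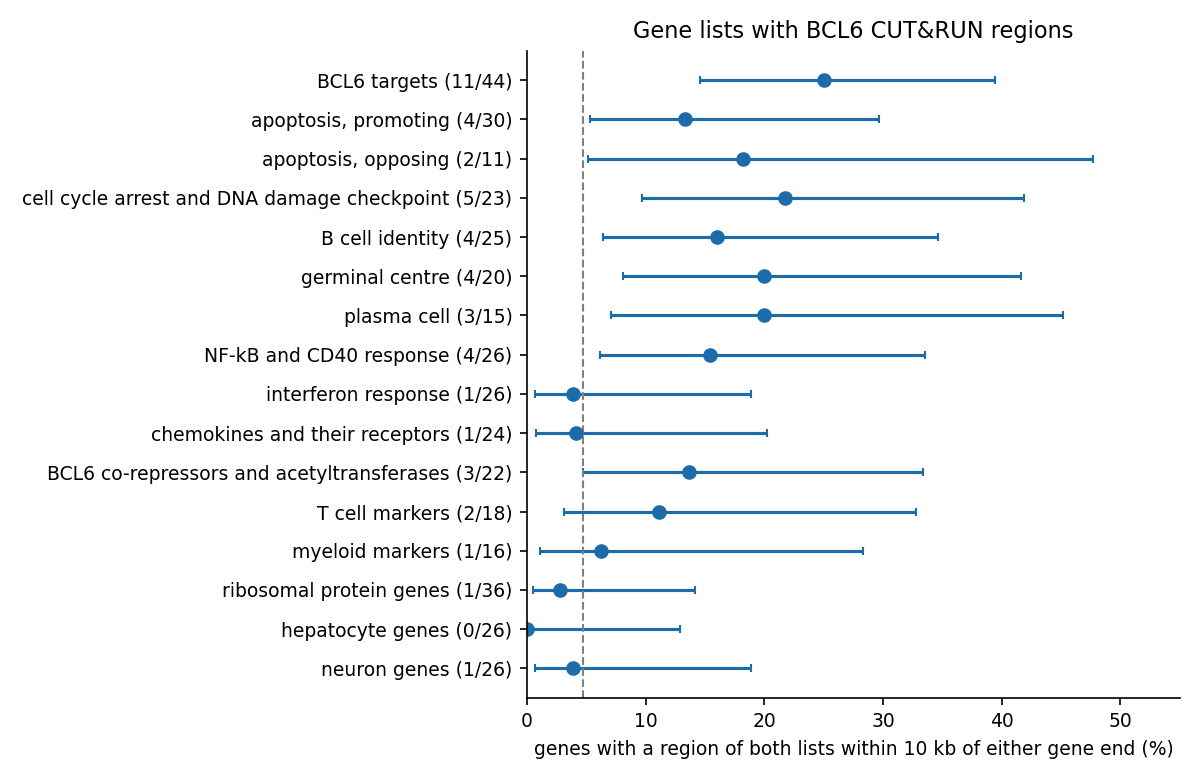
Percent of the members of each gene list with a reproducible summit within 10 kb of either gene end (horizontal axis), with members counted in brackets; bars are Wilson 95% intervals and the dashed line is the 4.72% of all protein-coding genes. BCL6 targets (25%) and cell cycle arrest genes (21.7%) passed the adjusted test, and the hepatocyte list is at 0.

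Of the genes followed whatever their values, several lacked a reproducible region nearby. For PRDM1, which encodes the plasma cell regulator BLIMP-1, the nearest lay inside the gene, 12.2 kb from its end, with fold enrichments of 4.25 and 5.40. For CCND2, encoding cyclin D2, it lay 15.5 kb outside, with 4.85 and 3.57. The protein-coding gene nearest to that region, named after its values were seen, was TIGAR at 387 bp. The nearest lay 82.5 kb from CDKN1A, although replicate 1 alone had a peak 11.6 kb from it (fold enrichment 2.44). For the BH3-only genes BBC3 and PMAIP1 the nearest reproducible regions were 434 kb and 4390 kb away, with a replicate 1 peak 2.74 kb from PMAIP1 (2.94). For IRF4 the nearest was 2448 kb away, and no peak of either list came closer than 299 kb. Few peaks with low pileups were found in both lists, so the lack of a reproducible region does not show that BCL6 was absent.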

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

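The test of neighbouring positions was set before its result was seen; the other tests given here were chosen after the results they bear on had been seen. The design names no second condition, so no biological explanation was tested by comparing groups.

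The mitochondrial genome, which the comparisons with genes leave out, held 5 reproducible regions. Fold enrichment there ranged from 1.44 to 3.68, and −log10 q reached 2472 in replicate 1 and 1769 in replicate 2, against at most 109 and 87.4 on chromosomes 1 to 22 and X. The lowest background recovered there was 238, among the 7 peaks there that counted as recovered.

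Most regions were in 1 list only. Counting noise near the calling threshold is a candidate explanation: of peaks with a −log10 q of at least 20, 92.1% were found in the other list for replicate 1, and 98.8% for replicate 2. With at least 10 these shares were 69.8% and 84.7%, and with at least 5 they were 42.7% and 59.1%. Many peaks well above the threshold were thus missed too, and noise near the threshold was not shown to account for them. A second explanation is that the replicates were called at neighbouring positions of one broader domain. A replicate 1 peak lay within 10 kb of 37.9% of the regions of replicate 2 only (95% interval 35.91 to 39.99), against 10.2% when these were moved by 50 to 150 kb, which is between the 50% and the 25% set as bounds, so this stays open. Both may hold for different regions.

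The BCL6 target list had regions more often than other genes. Open promoters of heavily used genes as the whole reason are argued against only by the ribosomal protein genes, which had reproducible regions at 2.78% against 25% (Fisher's exact p = 0.00938), although in replicate 1 alone it was 22.2% against 38.6% (Fisher's exact p = 0.148) and in replicate 2 alone 8.33% against 27.3% (Fisher's exact p = 0.0434), and histone genes, another heavily used class, went the other way with regions at 53 of 55. Chromatin that is open in B cells could account for part of it: B cell identity genes had regions at 16.0%, and the difference from the target list did not pass (Fisher's exact p = 0.546). In each list alone B cell identity genes had them more often than BCL6 targets, at 68.0% against 38.6% in replicate 1 and 40% against 27.3% in replicate 2. So did the germinal centre, cell cycle arrest, NF-kB and co-repressor lists. The small lists and the opposite order in the single replicates keep this open.

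Chromosome 12 had the most regions per megabase, 3.88 against 2.44 on the other autosomes, and 118 of its 517 regions were reproducible. Gene density alone is argued against, since 7 autosomes had more protein-coding genes per megabase. That these had fewer regions per megabase follows from chromosome 12 having been picked as the highest. More coverage from extra copies of chromosome 12 may contribute: the median background of its peaks was 1.46 times that of the other autosomes in replicate 1 (bootstrap 95% interval 1.29 to 1.55) and 1.43 times in replicate 2 (1.27 to 1.66), the highest of all autosomes in each. The median fold enrichment of its peaks was 0.939 and 0.936 times that of the others. Copy number itself was not measured, and backgrounds are known only where a peak was called.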

How the results depend on the processing

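The tests without mitochondrial and unplaced regions, without chromosome 12, with members at the same regions counted once and with each summit moved were chosen after the results had been seen. Of the 1350 replicate 1 peaks with a partner, 763 had one by reciprocal overlap of at least 50% and 863 by summits within 200 bp. The count of reproducible regions, 1316, became 484 and 200 with −log10 q of at least 5 and 10, where fewer peaks enter. The share of replicate 2 peaks found became 21.6%, 24.4%, 43.5% and 61.6% under the same settings and 32.4% with lists of equal length, each far above random placement. Without mitochondrial and unplaced regions these were 1311 and 38.4%. The rank agreement stayed positive, with rho from 0.469 to 0.498. The share near gene ends was 41.8% within 2 kb, 42.3% for ends of all genes, 39.2% and 40.5% with −log10 q of at least 5 and 10, and 28.5% to 31.4% in a single list. The 2 lists past the threshold became 7 within 50 kb, 4 with gene bodies, and 1 each with −log10 q of at least 5, of at least 10, without chromosome 12 and with members at the same regions counted once. With 1 replicate left out they were 6 to 7. Causes of these moves were not tested. The BCL6 target list passed in all 9 alternatives, but its counts did not change with members at the same regions counted once, so that setting did not test it. Over all 16 lists, 92 of 144 comparisons kept their side of the threshold and of other genes, 18 newly passed, and 6, all of the cell cycle arrest list, no longer did. Among those kept are all other lists with members at the same regions counted once, where their counts could not change. In 28 a list moved to the other side of other genes, none of them past the threshold in either test. Within 1 kb these were the lists opposing apoptosis and myeloid (0%) and ribosomal (2.78%), and within 50 kb myeloid (6.25%). In replicate 2 alone they were interferon (23.1%), chemokine (16.7%) and myeloid (6.25%), and in replicate 1 alone interferon (19.2%), T cell (11.1%), myeloid (6.25%) and ribosomal (22.2%). Chemokine genes in replicate 1 alone and ribosomal genes in replicate 2 alone were each at 8.33%. With −log10 q of at least 5 they were promoting apoptosis, NF-kB, co-repressor and myeloid (0%), interferon (3.85%), chemokine (4.17%) and ribosomal (2.78%). With at least 10 they were promoting and opposing apoptosis, B cell identity, NF-kB, co-repressor, T cell and myeloid (0%), chemokine (4.17%) and ribosomal (2.78%), and without chromosome 12 interferon (4.55%). No paired analysis was possible because values of the IgG libraries were not analysed here. The planned motif tests were not run, since no genome sequence was used. The median summit pileups of 23 and 21 limit the precision of each peak, and weak regions that were missed were not separated from false calls.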

Other observations

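The tests and gene groups in this part were all chosen after the results had been seen.

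Many replication-dependent histone genes had regions. Of 55 genes for H1, H2A, H2B, H3 and H4 on chromosome 6, taken by symbol between 25726063 and 27893891, 53 had a reproducible summit within 10 kb of an end, and 38 (69.1%) had one within 1 kb, against 2.45% of other protein-coding genes. H2AC1 and H2BC1 were the genes without one. The genes are packed closely and share regions, so they are not independent. The summits within 1 kb belonged to 38 distinct regions, 2.90% of all reproducible ones, with a median fold enrichment of 4.49 in replicate 1 and 4.93 in replicate 2. After H2AC12 and H1-3, the highest were at H4C12 (9.36 and 7.52) and H4C11 (7.27 and 8.46). Their median backgrounds, 6.08 and 4.76, were below the 7.84 and 5.93 of all reproducible regions.

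The interval between BCL6 and LPP on chromosome 3 held the group with the most called regions. Counting from 10 kb beyond the upper end of BCL6 to the lower end of LPP at 188153021, 48 regions were called, or 12.1 per 100 kb against 0.243 over the genome, and 16 were reproducible. The median background there was 7.58 in replicate 1 and 6.68 in replicate 2, against 5.90 and 4.63 for each whole list. Higher local coverage may therefore contribute to this density, and its part was not tested. Within this interval, 34 regions, 14 of them reproducible, lay between 187898794 and 188000506, where no protein-coding gene is annotated. Another group lay on chromosome 14 from 22476757 to 22532299 (16 regions, 2 reproducible). It held no protein-coding gene, and its midpoint was 60.4 kb from the nearest, DAD1. A further group lay at CD69 and CLECL1 on chromosome 12 (15 regions, 7 reproducible). Groups of 12 regions lay in NEK7 (3 reproducible), in FOXP1 (2 reproducible) and in ZNF608 (3 reproducible). Groups of 12 to 15 regions also lay at the histone genes of chromosome 6. A group of 17 regions in TOX, a transcription factor of lymphoid cells, had 14 in replicate 1, 3 in replicate 2 and 0 reproducible.

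The lists were also compared per gene, a looser rule. Of 2249 protein-coding genes with a replicate 2 summit within 10 kb, 1258 (55.9%) also had a replicate 1 summit, overlapping or not, where independent lists would give 342. For B cell identity genes it was 8 of 10, and POU2F1, IKZF1, PAX5 and IKZF3 had summits of each list within 10 kb but no reproducible one there. For germinal centre genes it was 7 of 11, with GCSAM, S1PR2 and P2RY8 in that position. Counted in this way, 6 lists passed. Germinal centre (35%), B cell identity (32%) and BCL6 target genes (25%) each had a Fisher's exact adjusted p of 7.72e-04, against 6.26% to 6.27% of other genes. Cell cycle arrest genes (30.4%), co-repressors and acetyltransferases (27.3%) and the NF-kB and CD40 response (23.1%) had Fisher's exact adjusted p-values of 0.00155, 0.00614 and 0.0127.

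Regions were also found near tRNA genes. Reproducible summits lay within 1 kb of an annotated tRNA gene in 11 cases (0.839%, Wilson 95% interval 0.469 to 1.496). Moving the summits by 10 to 50 kb gave 0.248% on average and at most 0.534%.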
